A study of Homo sapiens with 8 samples.

How the data were processed

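Messenger RNA of HT-29 cells, an established human colon adenocarcinoma line, was measured on 8 Agilent one-colour arrays (Cy3). Cells had been seeded at 10000 per 100 ul in 96-well plates, either in NanoCulture plates (NCP), whose culture surface carries a fine relief made for growing spheroids, or in flat polystyrene plates as a monolayer (2D), and were collected after 1 or 7 days. The labelled material was made from 0.5 ug of RNA. There were 2 arrays in each of the 4 groups, and groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so the spread between them may hold technical error alone. For NCP day 1 replicate 2 the description gives another day, while its title and growth condition both give day 1, and the title was followed.

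The submitters' processing notes name Agilent Feature Extraction 10.5.1.1. Per the file headers, the processed signal is an intensity from which local background was subtracted and spatial trends were removed within the array, with no scaling between arrays, and the headers place the probes on genome build hg18. The deposited mean signal and local background are intensities of pixel brightness, used in 1 alternative. The authors also deposited 3 tables made from group means. In these, the deposited fold is a ratio without sign, the deposited raw columns are mean intensity per group, and the deposited normalized columns are on the log2 scale. The table for NCP day 7 against NCP day 1 also holds a deposited p-value and a corrected p-value of a test that its header does not name. The authors' tables were compared with the fit and were used in no test.

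Processed signals were divided by each array's 75th percentile over non-control spots and put on the log2 scale, and spots of a probe not marked as outliers were averaged. Of 41000 non-control probes, 28851 entered because the software called them well above background on both arrays of at least 1 group, after 39 probes without a value had been left out. A gene was represented by its brightest entering probe, which gave 21034 genes, 13594 of them with a gene symbol. Probes were named by a current RefSeq accession (24794), a listed accession (287), a current symbol (2318) or an older symbol (820), and 12781 kept the name in the file. Where a group was not well above background, its level was raised to the dimmest value that the software called well above background on each of its arrays in the fit, and the fold is given as at least the resulting ratio. An interaction is bounded in the same way where each raise moves it towards 0, and is otherwise given no size. Genes and lists in which this was done are described as not well above background.

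Groups were compared with limma 3.58.1 in R 4.3.3 with the package data.table at version 1.17.8, with 4 group means in one fit, 4 residual degrees of freedom and 1.786 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. There were 5 comparisons: NCP against 2D at day 1 and at day 7, day 7 against day 1 in NCP and in 2D, and the plate by day interaction, which is the plate difference at day 7 minus that at day 1. An exact permutation of 2 against 2 arrays cannot go below a two-sided p of 0.333, so tests rest on the spread shared across groups and genes. Values after ± are standard errors with 2 arrays per group unless an array is said to be left out, in which case the lone array of that group is assumed to vary like the others. Correlations across genes are descriptions, since genes are not independent replicates.

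A total of 37 gene lists were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg over the lists of a comparison, each with at least 5 measured members. They were hypoxia response, glycolysis, oxidative phosphorylation, DNA replication, mitosis, cholesterol synthesis, fatty acid synthesis, unfolded protein response, amino acid response, interferon response, antigen presentation, inflammatory cytokines and NF-kB targets, p53 targets, apoptosis regulators, mesenchymal markers, epithelial junctions, matrix proteases and motility, cell-matrix adhesion, YAP and TEAD targets, SRF and actin cytoskeleton, ERK pathway output, immediate early genes, Wnt targets and crypt base, enterocyte differentiation, goblet and mucus, enteroendocrine, heat shock, NRF2 targets, metallothioneins, lysosome and autophagy, polyadenylated histones, ribosome biogenesis, xenobiotic metabolism and efflux, keratins, and fibroblast, endothelial and leukocyte markers. Lists share some members. With a correlation estimated from the 4 residual degrees of freedom, 0 lists were called in any comparison.

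The named genes are those with a symbol that had the 8 largest rises and falls among calls (4 for the interaction), the 3 called members with the largest change in each called list and the 1 with the largest change the other way, and the 2 members with the largest change in other lists. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Those alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, a variance trend with robust fitting, a fit on the compared groups alone, a replicate block, a fold of at least 2, camera with an estimated correlation, and leaving out each array in turn. Chosen after seeing the data were removal of the trend with probe GC content (a loess curve of span 0.5 per array), that removal together with leaving out the array labelled 2D day 1 replicate 2, a crossed replicate block, and the naming rule applied to the fit without that array.

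The arrays lie on 3 slides: slide 1 held the 4 day 1 arrays, slide 2 the 2D day 7 arrays and slide 3 the NCP day 7 arrays. A slide block could not be fitted beside the groups and was not run. The day 1 comparison lies within 1 slide, while the day 7, time and interaction comparisons cannot be told apart from a difference between slides. The number of arrays limits the precision. The pipeline was tested on simulated data in which 250 genes per fold size were changed over 5 runs. With the spread of all 4 groups, 31.6% of genes with a 2-fold change and 79.2% with an 8-fold change were recovered, with 26 false among 466 calls. With the spread of the 3 groups other than 2D day 1, these shares were 76.0% and 94.4%, with 47 false among 872 calls. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs, also with an estimated correlation. Genes varied independently in these runs, while in the data the estimated correlation reached 0.988 for the mitosis list. The runs therefore do not show how the list tests behave for correlated genes. A gene also had the same spread in all groups of a run, while in the data the spread within 2D day 1 was far larger than in the other groups. The shares recovered and the false calls therefore need not hold for the comparisons in the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.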

Results

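Transcript levels of HT-29 cells were compared between NanoCulture plates (NCP) and flat plates (2D) after 1 and 7 days of culture, and the series title gives the characterization of HT-29 cells in NCP as its purpose. HT-29 is an epithelial line from a colon adenocarcinoma that can take on traits of absorptive and mucus-secreting gut cells. Each of the 4 groups (2D day 1, NCP day 1, 2D day 7 and NCP day 7) had 2 arrays. Of 43376 non-control spots per array, 65.6% to 71.0% were well above background and 0 were saturated. The 75th percentile of the processed signal lay between 865 and 1252 on the first 6 arrays, and at 757 and 632 on the NCP day 7 arrays. NCP day 7 replicate 1 was the noisiest array. Its spike-in median coefficient of variation was 10.2%, against 3.24% to 5.37% on the others. For repeated non-control probes it was 7.05%, against 4.04% to 5.11%. The number of arrays limits the precision of every value.

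The 2 arrays labelled 2D day 1 differed from each other far more than the arrays of any other group. The interferon-induced gene IFI44L lay at a log2 level of -8.87 on 2D day 1 replicate 1, where it was not well above background, at 1.17 on the array labelled 2D day 1 replicate 2, and at 1.53 and 1.49 on the 2D day 7 arrays. MX1, an antiviral GTPase, lay at -3.35 and 3.90 on the 2D day 1 arrays and at 4.09 and 3.93 in 2D day 7. The S-phase cyclin CCNA2 went the other way, at 1.14 and -0.80 in 2D day 1 and at -1.08 and -1.09 in 2D day 7. INSIG1, a sensor of cellular sterols, lay at -0.97 and 1.52 in 2D day 1 and at 1.59 and 1.62 in 2D day 7. Across genes, the log2 differences between the 2D day 1 arrays had a standard deviation of 0.890, against 0.188 within 2D day 7, 0.267 within NCP day 1 and 0.393 within NCP day 7. The array labelled 2D day 1 replicate 2 differed from the 2D day 7 arrays by 0.267 and 0.285, and 2D day 1 replicate 1 differed from the NCP day 1 arrays by 0.396 and 0.404. There were 4008 genes at least 2-fold apart between the 2D day 1 arrays. All arrays were kept in the groups their labels give, and each comparison was also fitted without each 2D day 1 array. The fit without the array labelled 2D day 1 replicate 2 is called the 7-array fit.

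**Figure D1:**
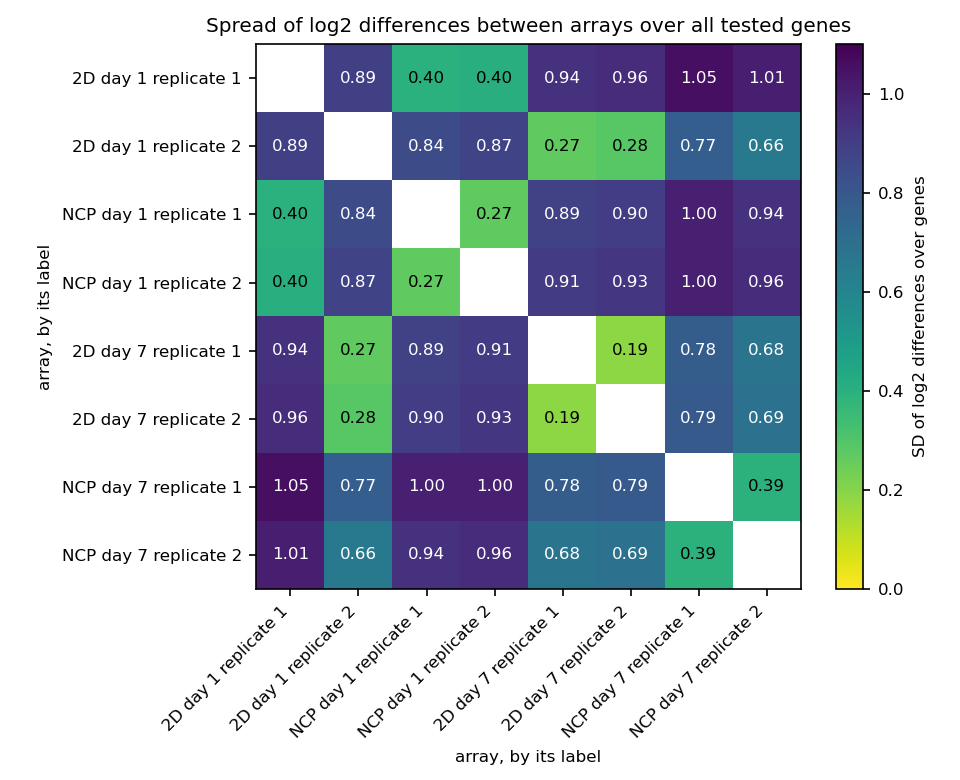
Standard deviation across genes of the log2 differences between each pair of the 8 arrays, as a heat map with arrays named by group and replicate. The 2D day 1 arrays differ by 0.890, while the array labelled 2D day 1 replicate 2 differs from the 2D day 7 arrays by 0.267 and 0.285.

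At day 7, the hypoxia and glycolysis lists were called higher in NCP than in 2D cells, and the growth control genes CCN1 and SPRY4 fell. The angiogenic growth factor VEGFA rose by a log2 fold change of 2.38 ± 0.14 (n = 2 per group, adjusted p = 0.00166), from levels of -0.47 and -0.36 in 2D to 2.01 and 1.93 in NCP. LDHA, which makes lactate, rose by 1.39 ± 0.19 (adjusted p = 0.0109). The neurotrophic factor ARTN rose by 6.12 ± 0.25 (adjusted p = 0.00161) and the fatty acid binding protein of absorptive gut cells FABP1 by 3.56 ± 0.36 (adjusted p = 0.00529). The neutrophil-attracting chemokine CXCL1 fell by 1.53 ± 0.14 (adjusted p = 0.00383). This comparison asks how the plate altered transcript levels after a week, and limma with Benjamini-Hochberg called 2578 of 21034 genes, 1752 higher and 826 lower in NCP, of which 1300 were at least 2-fold apart. The 2D day 1 arrays enter this comparison only through the shared spread, and the 7-array fit called 10575 genes, 5835 higher and 4740 lower, including each of the 2578 in the same direction. Leaving out 2D day 1 replicate 1 instead gives the same fit of this comparison, since a lone 2D day 1 array adds nothing to the spread. Without an array of another group the count fell below 2578. The share of calls that were higher depended on the setting, with 4158 of 4897 under normexp and 1327 of 2205 with the trend in probe GC content removed. Each plate's arrays shared a slide at day 7, so plate and slide cannot be told apart.

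Next to ARTN, the largest rises in NCP at day 7 included genes not well above background in 2D. GNG8, a G protein subunit, rose by 6.26 ± 0.47, and TBX1, a developmental transcription factor, by 5.18 ± 0.43. The inducible heat shock protein HSPA6 rose by 5.24 ± 0.54 and the folate carrier SLC46A1 by 5.14 ± 0.15 (adjusted p = 0.000529). FRRS1L, a partner of glutamate receptors, was at least 44.0-fold higher, the dynein chain DNAH17 at least 13.3-fold and the endopeptidase ECEL1 at least 6.64-fold, since 2D cells were not well above background for them. Among the falls, the interferon-induced genes RSAD2 and EPSTI1 were at least 11.6-fold and 5.39-fold lower. The interleukin antagonist IL36RN was at least 7.44-fold lower, the peptide hormone UTS2B at least 4.78-fold, the hair keratin KRT83 at least 2.62-fold and the growth factor TGFB2 at least 2.05-fold. USP18, which restrains interferon signalling, fell by 2.76 ± 0.57 (adjusted p = 0.0346), and its pseudogene USP41P fell by 2.64 ± 0.42. The probe of ARTN lies on hg18 chromosome 1 from 44174808 to 44174867 and that of VEGFA on chromosome 6 from 43860503 to 43860562. With the trend in probe GC content removed, RSAD2 had an adjusted p of 0.05 and was not called.

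Lists of genes for low oxygen and energy metabolism were called higher in NCP at day 7 at the preset correlation. Of 24 hypoxia response genes, 13 rose and 0 fell at day 7 (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.33 and a camera adjusted p of 1.1e-09, against an adjusted p = 0.532 with an estimated correlation. The vasodilator peptide ADM rose by 1.80 ± 0.20 and the collagen hydroxylase P4HA1 by 1.72 ± 0.15. The stress gene NDRG1 was higher by 3.22 ± 0.81 (adjusted p = 0.0574) and ANGPTL4, an inhibitor of lipoprotein lipase, by 2.66 ± 0.65 (adjusted p = 0.0527), and these were called in the 7-array fit (0.00209 and 0.00151). Of 20 glycolysis genes 7 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.65 and an adjusted p of 1.23e-05, against an adjusted p = 0.532 with an estimated correlation. PGK1 and GPI, enzymes of the pathway, rose by 1.14 ± 0.13 and 1.12 ± 0.19. In the 7-array fit 17 glycolysis genes rose and 1 fell, which was the muscle-type phosphofructokinase PFKM, by 0.22. Of 31 oxidative phosphorylation genes 2 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.28 and an adjusted p of 0.000761, against an adjusted p = 0.877 with an estimated correlation. UQCRB of respiratory complex III rose by 0.72 ± 0.10 and COX4I1 of the cytochrome oxidase by 0.42 ± 0.10.

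The interferon response was lower in NCP at day 7, most clearly in the 7-array fit. The 32 genes of this list had a median log2 fold change of -2.74, or -2.57 with bounds, and camera gave an adjusted p of 3.67e-08, against an adjusted p = 0.967 with an estimated correlation. With all 8 arrays 3 of them fell and 0 rose (0 and 0 adjusted over the list alone), and in the 7-array fit 31 fell and 0 rose. In that fit IFI44L was at least 166-fold lower, the mitochondrial protein IFI6 fell by 5.31 ± 0.06 (adjusted p = 0.000149), MX1 fell by 4.91 ± 0.08 (adjusted p = 0.000212) and the membrane protein IFITM1 by 6.56 ± 1.25 (adjusted p = 0.0137). With all 8 arrays IFI44L had an adjusted p of 0.151. Its probe lies on hg18 chromosome 1 from 78880178 to 78880237. Antigen presentation had a median of -0.66 and was not called (adjusted p = 0.13), and in the 7-array fit 3 of its genes rose and 11 fell (adjusted p = 0.0056, and adjusted p = 0.538 with an estimated correlation). The peptide transporter TAP1 fell by 2.03 in that fit and the proteasome subunit PSMB9 by 1.80, while CIITA, a switch for class II genes, rose by 1.28.

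Growth signalling and inflammatory lists were lower in NCP at day 7. Of 20 YAP and TEAD targets 4 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.33 and an adjusted p of 0.013, against an adjusted p = 0.532 with an estimated correlation. The matrix protein CCN1 fell by 0.80 ± 0.11 and the junction protein AJUBA by 0.87 ± 0.20. Among 21 ERK output genes 3 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.33 and an adjusted p of 0.0112, against an adjusted p = 0.532 with an estimated correlation. SPRED2 and SPRY4, feedback inhibitors of the pathway, fell by 0.82 ± 0.17 and 0.57 ± 0.11, and the cyclin CCND1 by 0.51 ± 0.10. Of 26 inflammatory cytokines and NF-kB targets 2 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.32 and an adjusted p of 0.0372, against an adjusted p = 0.985 with an estimated correlation. They were CXCL1 and the related chemokine CXCL5, which fell by 0.60 ± 0.11, and the list was not called with the GC trend removed (adjusted p = 0.0516).

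The enteroendocrine, unfolded protein response and DNA replication lists were called higher in NCP at day 7, though few or no members of the last 2 passed singly. Among 9 enteroendocrine genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 1.25 and an adjusted p of 0.0112, against an adjusted p = 0.532 with an estimated correlation. NEUROG3, which starts the endocrine fate, rose by 1.93 ± 0.26, the satiety hormone PYY by 1.75 ± 0.21 and the granule protein SCG3 by 1.31 ± 0.31. The median of this list was 0.58 with the GC trend removed. Of 20 unfolded protein response genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.48 and an adjusted p of 0.0276, against an adjusted p = 0.877 with an estimated correlation. CRELD2 rose by 1.52 ± 0.29 and SEL1L by 0.49 ± 0.11. The 32 DNA replication genes had a median of 0.54 and an adjusted p of 0.0277, against an adjusted p = 0.985 with an estimated correlation, and none passed singly either over all genes or adjusted over the list alone. In the 7-array fit 29 of them rose and 0 fell, with the origin protein ORC1 higher by 0.92 and the helicase subunit MCM6 by 0.81.

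Lists of genes typical of other cell types gave mixed results at day 7. Of 10 leukocyte markers 5 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.88 and an adjusted p of 0.0372, against an adjusted p = 0.877 with an estimated correlation. NKG7 rose by 1.85 ± 0.30, CD4 by 1.82 ± 0.16 and CD14 by 1.41 ± 0.27, and the list was not called in the 7-array fit (adjusted p = 0.15). Fibroblast markers had a median of 0.20 and were not called (adjusted p = 0.771), although DPT and THY1 rose, the latter by 1.45 ± 0.14. Endothelial markers had a median of -0.14 while camera pointed up (adjusted p = 0.981), and CLDN5 rose by 1.89 ± 0.32 and ERG by 0.92 ± 0.14.

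The remaining lists were not called at day 7, though single members changed. Mesenchymal markers had a median of 0.33 (adjusted p = 0.399), with FOXC2 higher by 1.89 ± 0.22 and TWIST1 by 1.41 ± 0.20. Epithelial junctions had a median of 0.08 (adjusted p = 0.642), with the tight junction protein CLDN1 lower by 1.32 ± 0.12 and the gut cadherin CDH17 higher by 0.87 ± 0.19. Enterocyte differentiation had a median of 0.30 (adjusted p = 0.399), and goblet and mucus genes one of 0.09 (adjusted p = 0.306), where the mucin MUC5B rose by 3.22 ± 0.36 and AGR3 by 2.61 ± 0.18. For Wnt targets and crypt base the median was -0.12 (adjusted p = 0.168), and the Wnt inhibitor DKK1 fell by 1.70 ± 0.25. Matrix proteases and motility had a median of 0.16 (adjusted p = 0.693), with MMP28 higher by 1.85 ± 0.21 and MMP7 lower by 1.34 ± 0.14. Cell-matrix adhesion had a median of -0.10 (adjusted p = 0.0795). Keratins had a median of 0.20 (adjusted p = 0.654), and KRT17, a keratin of stressed and wounded epithelium, fell by 1.67 ± 0.30 (adjusted p = 0.0232). Its probe lies on hg18 chromosome 17 from 37030502 to 37030561. SRF and actin cytoskeleton genes had a median of 0.10 while camera pointed down (adjusted p = 0.771), and the actin-binding CALD1, at least 2.24-fold lower, had a log2 fold change of 0.04 under normexp background correction.

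Apoptosis regulators had a median of -0.14 at day 7 and were not called (adjusted p = 0.759), though the death activator HRK rose by 3.11 ± 0.24 and the survival factor BCL2 by 0.93. Immediate early genes had a median of 0.14 (adjusted p = 0.693), with FOS higher by 1.34 ± 0.21. NRF2 targets had a median of -0.01 (adjusted p = 0.642), with the cystine carrier SLC7A11 lower by 1.14 ± 0.15. For heat shock the median was -0.04 (adjusted p = 0.771), with CRYAB higher by 1.11, and for metallothioneins it was 0.11 (adjusted p = 0.511), with MT3 higher by 1.03. Lysosome and autophagy had a median of 0.04 with camera pointing down (adjusted p = 0.771), and LAMP2 fell by 0.83. Polyadenylated histones had a median of 0.12 (adjusted p = 0.642), with H1-2 higher by 0.79. Medians for p53 targets (0.18, adjusted p = 0.981) and ribosome biogenesis (0.07, adjusted p = 0.771) were positive while camera pointed down, and the p53 target PLK2 fell by 0.83. Mitosis (median 0.14), cholesterol synthesis (-0.02) and xenobiotic metabolism and efflux (-0.13) each had an adjusted p of 0.771. Fatty acid synthesis had a median of 0.09 (adjusted p = 0.931) and the amino acid response one of -0.10 (adjusted p = 0.759).

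Rises in NCP at day 7 were more frequent among genes whose probes were rich in G and C. For 477 genes with a probe of more than 65% GC, such as ARTN with 73.3%, the median log2 fold change was 0.77 and 39.6% were at least 2-fold higher. For 3536 genes with a probe under 35% GC the median was -0.17 and 1.24% were at least 2-fold higher. Relative to each gene's mean over all arrays, levels on both NCP day 7 arrays rose with GC content, by 0.190 and 0.166 per 10 percentage points. On the other 6 arrays these relative levels fell by 0.042 to 0.098. Deviations from a common mean offset one another, so these falls do not show that the levels themselves fell with GC content. Among 5768 pairs of probes for the same gene, the log2 fold change at day 7 rose by 0.191 per 10 points between the probes of a gene (95% interval 0.176 to 0.207), against 0.208 across those genes. In NCP over time these slopes were 0.068 (0.0495 to 0.0866) and 0.291, and in 2D over time -0.132 and 0.0796. With this trend removed, HRK was higher by 2.27 and limma called 2205 genes at day 7 with Benjamini-Hochberg.

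**Figure D2:**
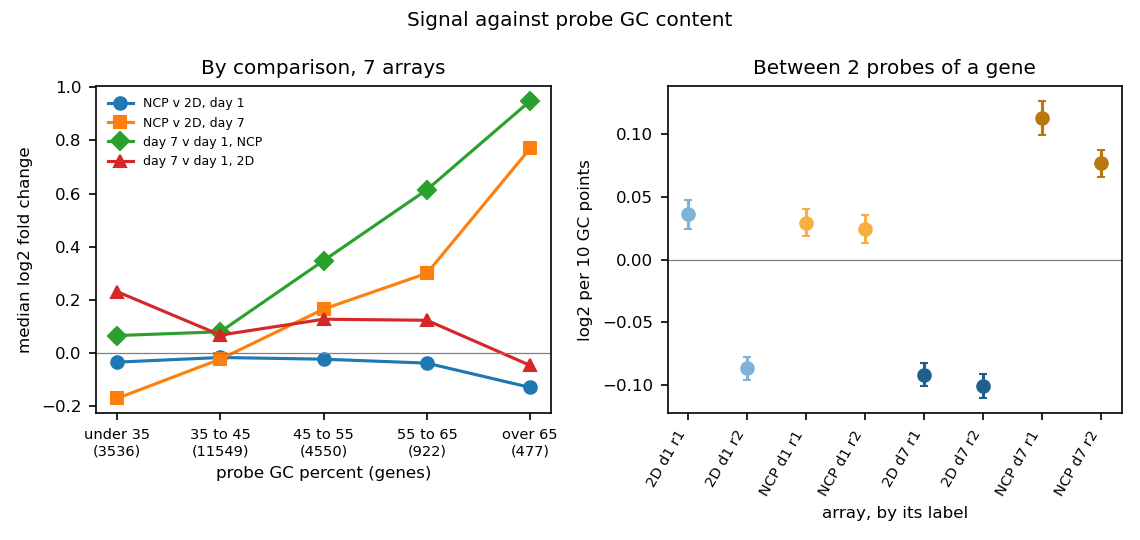
Left, median log2 fold change of genes by the GC content of their probe for each comparison in the 7-array fit. Right, for each array, slope of the log2 level per 10 percentage points of GC between probes of the same gene. These levels are relative to the mean over all arrays. The NCP day 7 arrays lie at 0.113 and 0.077 and the 2D day 7 arrays at -0.092 and -0.101.

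From day 1 to day 7 in NCP, the hypoxia and cholesterol synthesis lists were called higher, and the keratin, mitosis and ribosome biogenesis lists lower. TBX1 rose by 7.11 ± 0.43 (n = 2 per group, adjusted p = 0.00163), ARTN by 6.35 ± 0.25 (adjusted p = 0.00133) and the stress gene NDRG1 by 5.01 ± 0.81 (adjusted p = 0.0129). KRT17 fell by 4.80 ± 0.30 (adjusted p = 0.00178) and KRT16, another keratin of stressed epithelium, by 4.51 ± 0.25 (adjusted p = 0.00152). The comparison asks how transcripts changed over a week in these plates, and limma with Benjamini-Hochberg called 5484 genes, 3731 higher and 1753 lower at day 7, with 2856 at least 2-fold apart. The 7-array fit called more genes, including each of the 5484 in the same direction. Leaving out 2D day 1 replicate 1 instead gives the same fit of this comparison, since a lone 2D day 1 array adds nothing to the spread. Without an array of another group the count fell below 5484. The days were on separate slides. The median log2 fold change of all genes was 0.171, against -0.086 with scaling to the median.

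Several of the largest rises were in genes not well above background in NCP at day 1. The hormone SST was at least 20.2-fold higher at day 7, the brush border protease MEP1A at least 30.6-fold, the hypoxia-induced COXFA4L2 at least 47.9-fold, MS4A8 at least 23.3-fold and the calcium-binding CHP2 at least 20.6-fold. GNG8 rose by 6.22 ± 0.47 and FABP1 by 4.64 ± 0.36. The keratin pseudogene KRT17P3 fell by 4.95 ± 0.35. The scaffold protein AKAP12 was at least 13.7-fold lower, the actin-like ACTL8 at least 7.44-fold, the membrane protein LRRN4 at least 6.21-fold, KRT83 at least 4.79-fold and the caveolar CAV3 at least 4.69-fold. MUC5B rose by 3.47 ± 0.36, while SPINK4, which goblet cells secrete, was at least 4.51-fold lower and the gut hormone CCK at least 4.62-fold. The enteroendocrine and enterocyte lists were not called (adjusted p = 0.0671 and 0.131).

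Of 24 hypoxia genes 22 rose and 0 fell in NCP over the week (22 and 0 adjusted over the list alone), with a median of 1.62 and a camera adjusted p of 3.81e-08, against an adjusted p = 0.726 with an estimated correlation. ANGPTL4 rose by 3.75 ± 0.65 and the glycolytic regulator PFKFB4 by 3.37 ± 0.54. Glycolysis had a median of 0.37 with 8 genes higher and was not called (adjusted p = 0.121), with ALDOC higher by 4.37 ± 0.64 and ENO2 by 1.66 ± 0.25. Of the cholesterol synthesis genes 7 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.98 and an adjusted p of 0.00209, against an adjusted p = 0.8 with an estimated correlation. INSIG1 rose by 2.94 ± 0.74, the sterol carrier STARD4 by 2.01 ± 0.46 and the enzyme DHCR7 by 1.66 ± 0.35. The lipid regulator SREBF1 rose by 2.79 ± 0.58 and ACSS2, which makes acetyl-CoA, by 3.50 ± 0.90.

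The lists of cell division genes were called lower in NCP at day 7 than at day 1, though few members passed singly. Of the mitosis genes 5 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.99 and an adjusted p of 3.81e-08, against an adjusted p = 0.75 with an estimated correlation. The spindle checkpoint kinase TTK fell by 1.49 ± 0.39, and the centromere proteins CENPA and CENPE by 1.29 ± 0.34 and 1.08 ± 0.30. DNA replication had a median of -0.91 with no gene passing singly or adjusted over the list alone (adjusted p of the list 1.98e-06, and adjusted p = 0.75 with an estimated correlation), and 32 of its genes fell in the 7-array fit. Of the ribosome biogenesis genes 4 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.62 and an adjusted p of 2.11e-06, against an adjusted p = 0.75 with an estimated correlation. The nucleolar proteins NOP56, UTP20 and WDR43 fell by 1.06 ± 0.28, 0.97 and 0.90.

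Keratin and actin cytoskeleton lists were lower at day 7 in NCP. Of the keratins 7 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.51, or -0.15 with bounds, and an adjusted p of 0.00323, against an adjusted p = 0.419 with an estimated correlation. The cornified envelope protein SPRR1B fell by 3.40 ± 0.55, and KRT80, a member of the SRF and actin list, by 2.54 ± 0.21. The probe that stood for KRT14 rose by 1.12 ± 0.12, while the mean of the gene's probes fell, so its probes disagreed in direction. Under normexp, where the brightest probe was chosen anew, KRT14 lay at -3.26. The direction of this gene is therefore not settled. Of the SRF and actin genes 7 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.35 and an adjusted p of 0.00209, against an adjusted p = 0.419 with an estimated correlation. The actin crosslinker FLNA fell by 2.21 ± 0.35, CALD1 was at least 1.66-fold lower, and TPM2 rose by 0.89 ± 0.22. Under normexp CALD1 had a log2 fold change of 0.21. Cell-matrix adhesion had a median of -0.01 with 7 genes lower and was not called (adjusted p = 0.0504). Its member CAV1 fell by 3.04 ± 0.72. Of the YAP and TEAD targets, MYOF fell by 1.66 and CCN1 by 1.48 ± 0.11. Mesenchymal markers were not called (adjusted p = 0.305), with the matrix protein TNC at least 5.61-fold and VIM at least 1.81-fold lower, the latter at 0.17 under normexp. Epithelial junctions had a median of 0.15 (adjusted p = 0.904), with CLDN1 lower by 1.30 and TJP3 higher by 1.73.

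The NRF2, xenobiotic, heat shock and metallothionein lists were called lower in NCP at day 7 than at day 1, with a minority of NRF2, xenobiotic and heat shock genes passing singly. Of the NRF2 targets 8 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.74 and an adjusted p of 1.23e-05, against an adjusted p = 0.75 with an estimated correlation. The efflux pump ABCC2 fell by 2.56 ± 0.63 and the glutathione synthesis subunit GCLM by 1.89 ± 0.44. Xenobiotic genes fell in 8 cases and rose in 2 (8 and 2 adjusted over the list alone), with a median of -0.25 and an adjusted p of 0.00885, against an adjusted p = 0.726 with an estimated correlation. The oxidase CYP1A1 fell by 3.65 ± 0.66, ALDH1A3 by 3.32 ± 0.60 and ALDH3A1 by 3.05 ± 0.68, and CYP2B6 rose by 1.64 ± 0.45. Heat shock genes fell in 5 cases and rose in 1 (12 and 2 adjusted over the list alone), with a median of -0.62 and an adjusted p of 0.000596, against an adjusted p = 0.75 with an estimated correlation. The chaperones STIP1, CHORDC1 and HSPH1 fell by 1.27 ± 0.31, 1.17 and 1.15 ± 0.27, and CRYAB rose by 0.64. Metallothioneins fell in 6 cases and rose in 1 (8 and 2 adjusted over the list alone), with a median of -0.42 and an adjusted p of 0.00885, against an adjusted p = 0.75 with an estimated correlation. MT1B, MT1H and MT1X fell by 0.83 ± 0.15, 0.69 and 0.61, and MT3 rose by 1.19 ± 0.13.

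**Figure D3:**
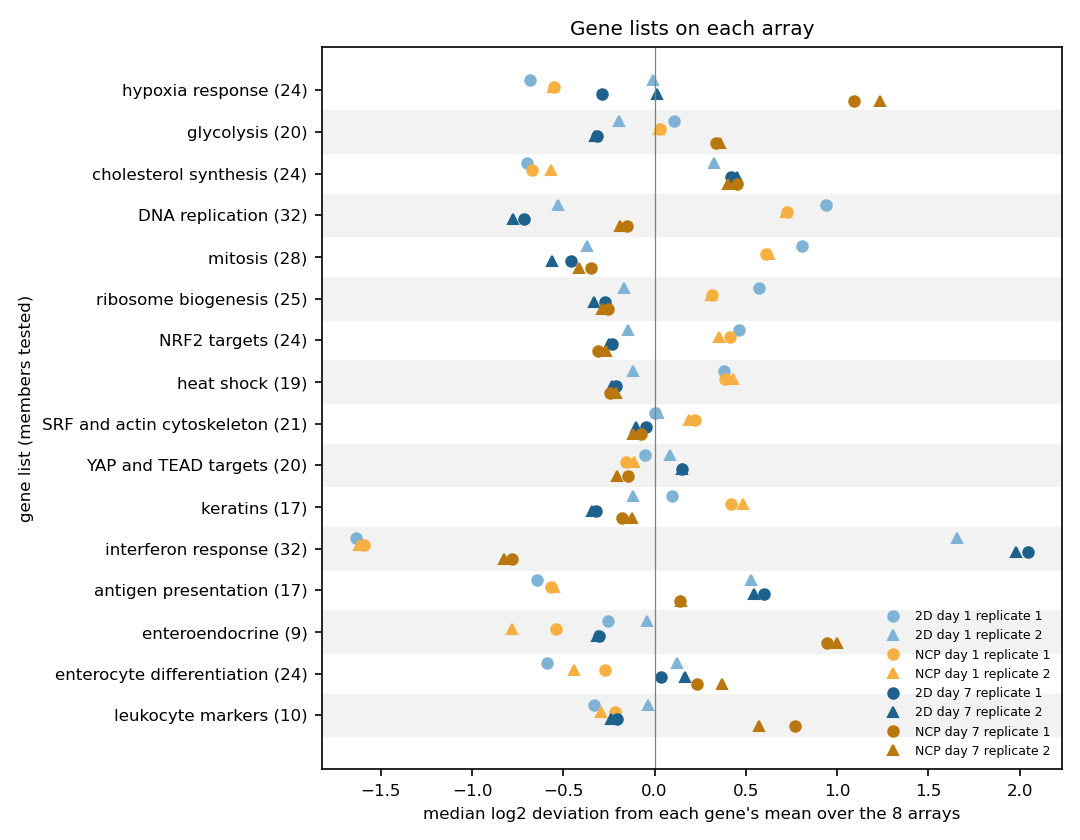
Median log2 deviation from each gene's mean over the 8 arrays for 16 gene lists, 1 value per list and array. The hypoxia list lies at 1.09 and 1.24 on the NCP day 7 arrays, and the interferon list at -1.64 and 1.66 on the 2D day 1 arrays.

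At day 1, only 3 genes passed between NCP and 2D with all 8 arrays, and more passed in the 7-array fit. GAS7, an actin-binding protein of neurons, was at least 2.02-fold higher in NCP (adjusted p = 0.0327). The neurotrophic factor NRTN was at least 1.80-fold and the pseudogene DUX4L8 at least 1.90-fold lower (adjusted p = 0.0327 for each). Their probes lie on hg18 chromosome 17 from 9760099 to 9760158 for GAS7, chromosome 19 from 5779120 to 5779179 for NRTN and chromosome 3 from 75800826 to 75800884 for DUX4L8. This comparison asks how the plate acted within a day, and limma with Benjamini-Hochberg called these 3 of 21034 genes, with 2345 at an unadjusted p under 0.05. All 3 were lost under normexp, quantile normalization, scaling to the median, no filter, a variance trend with robust fitting and the compared groups alone. They were also lost with the replicate block, the crossed block and removal of the GC trend. Leaving out any single array of a group other than 2D day 1 lost them too. GAS7 had a log2 fold change of 0.0071 under normexp (limma adjusted p = 0.967). With the GC trend removed its limma adjusted p was 0.0824, and no size is given since 2D day 1 was not well above background. The 7-array fit called 942 genes, 667 higher and 275 lower. Leaving out 2D day 1 replicate 1 instead gave 11651 calls.

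The following day 1 values come from the 7-array fit, in which 1 array stood for 2D day 1, and none of the single genes passed with all 8 arrays. KRT16 rose in NCP by 2.12 ± 0.11 (adjusted p = 0.012) and KRT17 by 1.97 ± 0.10, and with all 8 arrays they were higher by 2.51 and 2.45 (adjusted p = 0.124 and 0.168). Without 2D day 1 replicate 1 they rose by 2.89 and 2.93. The vasoconstrictor EDN2 was at least 5.23-fold and the globin HBB at least 3.36-fold higher, and SECTM1 rose by 2.59 ± 0.11, against -2.01 without replicate 1. DZIP1, a cilium protein, was at least 6.85-fold lower, and lay at -3.93 and -3.92 on the arrays labelled 2D day 1. SELENOM fell by 2.62 ± 0.26 and the transcription factor CEBPA fell by 2.19. Without replicate 1 SELENOM lay at -1.40 and CEBPA at -0.70, the latter without passing. Keratins rose in 6 cases and fell in 0 (7 and 0 adjusted over the list alone, adjusted p = 1.5e-05), immediate early genes in 8 cases (12 adjusted over the list alone, adjusted p = 8.4e-06) and epithelial junctions in 6 (16 adjusted over the list alone, adjusted p = 7.5e-08). For each of these lists the adjusted p = 0.262 with an estimated correlation. The early genes ATF3 and FOSB rose by 1.79 ± 0.07 and 1.19 ± 0.07, and the junction genes CDH17 and OCLN by 1.49 ± 0.11 and 1.15 ± 0.11. Without replicate 1 ATF3 lay at 0.28, FOSB at 0.79, CDH17 at 0.997 and OCLN at -0.03, and keratins were still called higher (adjusted p = 0.00047) and epithelial junctions and immediate early genes were not called (adjusted p = 0.352 and 0.817). Goblet genes rose in 7 cases (9 adjusted over the list alone, adjusted p = 2.4e-05) and metallothioneins in 4 (9 adjusted over the list alone, adjusted p = 6.4e-06), and for both the adjusted p = 0.331 with an estimated correlation. REG4 rose by 1.84 ± 0.20 and MT1F by 1.38 ± 0.08, and without replicate 1 they lay at 1.17 and -0.73, where the goblet list had a median of -0.18 and was not called (adjusted p = 0.938).

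With all 8 arrays camera called 19 lists at day 1, and 7 kept their call and direction in the 7-array fit. These 7 were higher in NCP, namely epithelial junctions (median 0.13), cell-matrix adhesion (0.06), SRF and actin cytoskeleton (0.13), immediate early genes (0.04), goblet and mucus (-0.04, opposite to the test), metallothioneins (0.35) and keratins (0.41). Their adjusted p ran from 7.12e-07 for keratins to 0.0334 for immediate early genes. Without replicate 1, epithelial junctions, cell-matrix adhesion (adjusted p = 0.444), immediate early genes and goblet genes were not called. With an estimated correlation none of the 7 was called, at an adjusted p = 0.126 with an estimated correlation for keratins and SRF genes, 0.62 for metallothioneins and 0.712 for the other 4. No gene of any of the 19 lists passed singly with all 8 arrays, while adjusted over the list alone 5 keratins, 5 metallothioneins, 4 SRF genes, 3 immediate early genes, 3 goblet genes and 1 junction gene were higher. DNA replication had a median of 0.46 (adjusted p = 1.72e-06, and adjusted p = 0.712 with an estimated correlation), against -0.18 in the 7-array fit and 1.23 without 2D day 1 replicate 1. The interferon response had a median of -1.62 (adjusted p = 0.000345, and adjusted p = 0.712 with an estimated correlation), against 0.18 and -3.37. Its member OAS1 rose by 1.06 ± 0.07 in the 7-array fit and lay at -2.34 without replicate 1.

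The other 12 lists called at day 1 with all 8 arrays had no gene that passed and did not keep a call in the same direction in the 7-array fit. Several turned the opposite way in that fit. Medians there were -0.18 for DNA replication, -0.12 for mitosis, -0.20 for ribosome biogenesis, -0.11 for NRF2 targets and 0.18 for interferon response, and camera pointed the same way as these medians. With all 8 arrays mitosis (median 0.47, camera adjusted p = 7.12e-07), oxidative phosphorylation (0.13), heat shock (0.22), NRF2 targets (0.14), ribosome biogenesis (0.12) and xenobiotic metabolism (0.24) were higher. Cholesterol synthesis (-0.48), amino acid response (-0.24), antigen presentation (-0.69) and inflammatory cytokines (-0.61) were lower with all 8 arrays. Adjusted over the list alone, 2 xenobiotic genes and 1 inflammatory gene were higher among them. For xenobiotic metabolism the adjusted p = 0.62 with an estimated correlation, and for the others it was 0.712 or 0.713. The p53 targets (adjusted p = 0.0013) and lysosome and autophagy (adjusted p = 6.6e-06) were called higher in the 7-array fit alone, at an adjusted p = 0.262 and 0.337 with an estimated correlation, with TP53INP1 higher by 1.96 ± 0.10 and GABARAPL1 by 0.96. Without replicate 1 these genes lay at -1.85 and -0.55.

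Between day 1 and day 7 in 2D, no gene passed with all 8 arrays, and the array labelled 2D day 1 replicate 2 decided the result. In the 7-array fit IFI44L was at least 272-fold higher at day 7 (adjusted p = 0.000137), IFI6 rose by 7.86 ± 0.07 (adjusted p = 6.95e-05) and MX1 by 7.36 ± 0.10 (adjusted p = 0.00013). Without 2D day 1 replicate 1 the same genes lay at 0.34, 0.06 and 0.11. This comparison asks how transcripts changed over a week in flat plates. With limma and Benjamini-Hochberg 0 genes were called over all 8 arrays (1712 at an unadjusted p under 0.05), 0 without replicate 1 (2581 at an unadjusted p under 0.05) and 12069 in the 7-array fit, 7182 higher and 4887 lower. Every alternative that kept all 8 arrays also gave 0.

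In the 7-array fit, antiviral and sterol genes rose in 2D over the week and cell cycle genes fell. IFITM1 was at least 1360.3-fold higher, OAS2 at least 54.9-fold, RTP4 at least 52.6-fold and the inflammatory protease CASP1 at least 46.9-fold, and all 32 interferon genes rose (camera adjusted p = 1.6e-14, and adjusted p = 0.264 with an estimated correlation). INSIG1 rose by 2.58 ± 0.06, and most cholesterol synthesis genes rose with it. On the array labelled 2D day 1 replicate 2, INSIG1 already lay at 1.52, against 1.59 and 1.62 on the 2D day 7 arrays. The replication factor MCM10 fell by 2.51 ± 0.06, CCNA2 by 2.23 ± 0.09 and SKP2, which drives entry into S phase, by 3.71 ± 0.13. All 32 replication genes fell, where without replicate 1 their median was -0.24. DZIP1 was at least 7.02-fold lower, and unlike the genes above lay at like levels on the arrays labelled 2D day 1, at -3.93 and -3.92. ABCC2 and AKR1C1 of the NRF2 targets fell by 2.59 and 2.46. The chemokines CXCL11 and CCL20 were at least 7.83-fold and 12.1-fold higher. The interferon list also lay higher in NCP at day 7 than at day 1. Its medians there, relative to each gene's mean over the 8 arrays, were -0.78 and -0.83, against -1.59 and -1.62.

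With all 8 arrays camera called 17 lists in 2D over time, 7 higher and 10 lower at day 7, and each had an adjusted p = 0.605 with an estimated correlation. The higher ones were interferon response (median 2.02, adjusted p = 1.57e-07), cholesterol synthesis (0.59), antigen presentation (0.74), inflammatory cytokines (0.43), epithelial junctions (0.16), immediate early genes (0.33) and lysosome and autophagy (0.33). The lower ones were DNA replication (-0.98, adjusted p = 1.37e-10), mitosis (-0.70), ribosome biogenesis (-0.47), NRF2 targets (-0.41), heat shock (-0.37), keratins (-0.27), unfolded protein response (-0.24), glycolysis (-0.20), oxidative phosphorylation (-0.18) and metallothioneins (-0.17). None of their genes passed over all genes or adjusted over the list alone, and 16 of the 17 kept their call and direction in the 7-array fit, metallothioneins being the exception (adjusted p = 0.51). Without replicate 1 only 9 of the 17 kept their call, and the interferon median was 0.20.

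The plate difference was more positive at day 7 than at day 1 for hypoxia and enteroendocrine lists, and more negative for single keratins such as KRT17. ARTN had an interaction of 6.51 ± 0.35 (n = 2 per group, adjusted p = 0.00652), GNG8 one of 6.49 ± 0.66 (adjusted p = 0.012) and FRRS1L one of at least 5.84 (adjusted p = 0.00652), since it was not well above background in 2D day 7. DNAH17 was called too (adjusted p = 0.0208), but only NCP day 7 was well above background, so that no size is given. KRT17P3, KRT17 and KRT16 had interactions of -4.44 ± 0.49, -4.12 ± 0.43 and -4.004 ± 0.358, and KRT83 one of -2.06 or lower, since it was not well above background in NCP day 7. KRT17 lay at -0.42 and -1.38 in 2D and at 1.47 and 1.62 in NCP at day 1, and at -1.54 and -1.62 in 2D and -3.31 and -3.20 in NCP at day 7. This comparison asks if the plate effect depended on the day. At day 7 each plate lay on a slide of its own, so plate and slide cannot be told apart in the interaction. Limma with Benjamini-Hochberg called 1022 genes, 818 positive and 204 negative. The 7-array fit called 5882, including each of the 1022 in the same direction, and of these 3423 were positive and 2459 negative. With the GC trend removed in addition, 2532 were positive and 2579 negative, and so the excess of positive calls depended on these choices. Leaving out an NCP day 1 or 2D day 7 array left 1 to 4 calls, and leaving out an NCP day 7 array left 215 or 633.

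Of 24 hypoxia genes 8 had a positive interaction and 0 a negative one (17 and 0 adjusted over the list alone), with a median of 1.54 and an adjusted p of 1.18e-09. VEGFA had 2.67 ± 0.19, the carbonic anhydrase CA9 2.66 ± 0.43 and the oxygen sensor EGLN3 1.78 ± 0.33. Glycolysis had a median of 0.63 with PFKL, at 0.80 ± 0.15, its 1 called gene (10 adjusted over the list alone, adjusted p = 0.000297). Enteroendocrine genes had a median of 1.37 with 3 called (6 adjusted over the list alone, adjusted p = 0.00737), NEUROG3 at 2.75 ± 0.37, PYY at 2.17 ± 0.29 and CHGA at 1.37 ± 0.21. Cell-matrix adhesion (-0.13, adjusted p = 0.00435), YAP and TEAD targets (-0.24, adjusted p = 0.0349), SRF and actin genes (-0.24, adjusted p = 0.00799) and keratins (-0.55, adjusted p = 0.0435) were negative. LAMA3 had -1.05 ± 0.15, CCN1 -1.60 ± 0.16, KRT80 -2.20 ± 0.30 and SPRR3 -1.79 ± 0.22, and KRT14 was positive at 1.46 ± 0.17, but lay at -2.65 under normexp and at -1.21 with the mean of its probes. Adjusted over the list alone, 1, 1, 2 and 3 genes of these 4 lists were negative, as over all genes. Each of these 7 lists had an adjusted p = 0.431 with an estimated correlation. With the GC trend removed, EGLN3, PFKL, KRT80, NEUROG3 and CHGA were not called.

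The other 5 interaction lists had an estimated-correlation p above that of the former 7. Leukocyte markers had a median of 0.96 with 4 genes positive (5 adjusted over the list alone), at an adjusted p of 0.0415 and an adjusted p = 0.779 with an estimated correlation. NKG7 had 2.33 ± 0.42, CD4 1.90 ± 0.23 and CD79A 1.38 ± 0.17, and the list was not called in the 7-array fit. Interferon response (-1.32, adjusted p = 0.00435), mitosis (-0.33, adjusted p = 0.0106) and NRF2 targets (-0.19, adjusted p = 0.0349) had no gene that passed, over all genes or adjusted over the list alone, and for each the adjusted p = 0.875 with an estimated correlation. Xenobiotic genes (-0.19, adjusted p = 0.0349) had an adjusted p = 0.495 with an estimated correlation. In the 7-array fit the interferon median was -2.83 with 30 genes negative, and without replicate 1 it was 0.70. MX1 had -5.65 ± 0.13 in the 7-array fit and 1.60 without replicate 1, and the mitosis median was 0.27 in the 7-array fit. Of the 12 called lists, 8 and 6 kept their call without NCP day 7 replicate 1 or 2, and 9 with the GC trend removed. Keratins were among those lost without either array (adjusted p = 0.104 and 0.0728), and YAP and TEAD targets were lost without replicate 2 and with the GC trend removed (0.161 and 0.0855).

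**Figure D4:**
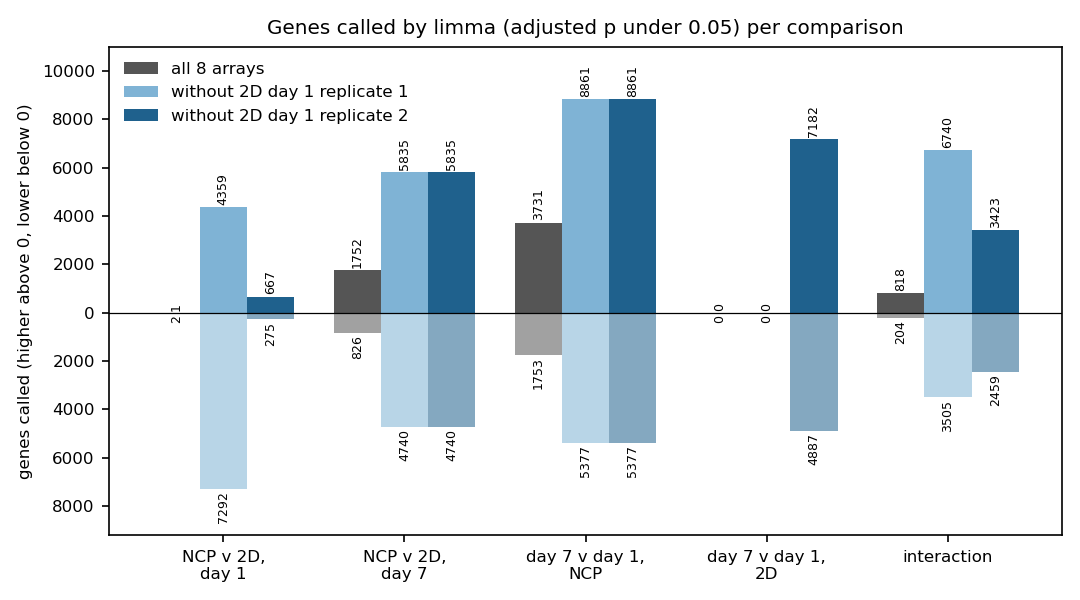
Number of genes called higher (above 0) and lower (below 0) in each comparison with all 8 arrays and without each 2D day 1 array, at a Benjamini-Hochberg adjusted p under 0.05. With all 8 arrays 2578 genes were called between the plates at day 7 and 0 between the days in 2D.

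**Figure D5:**
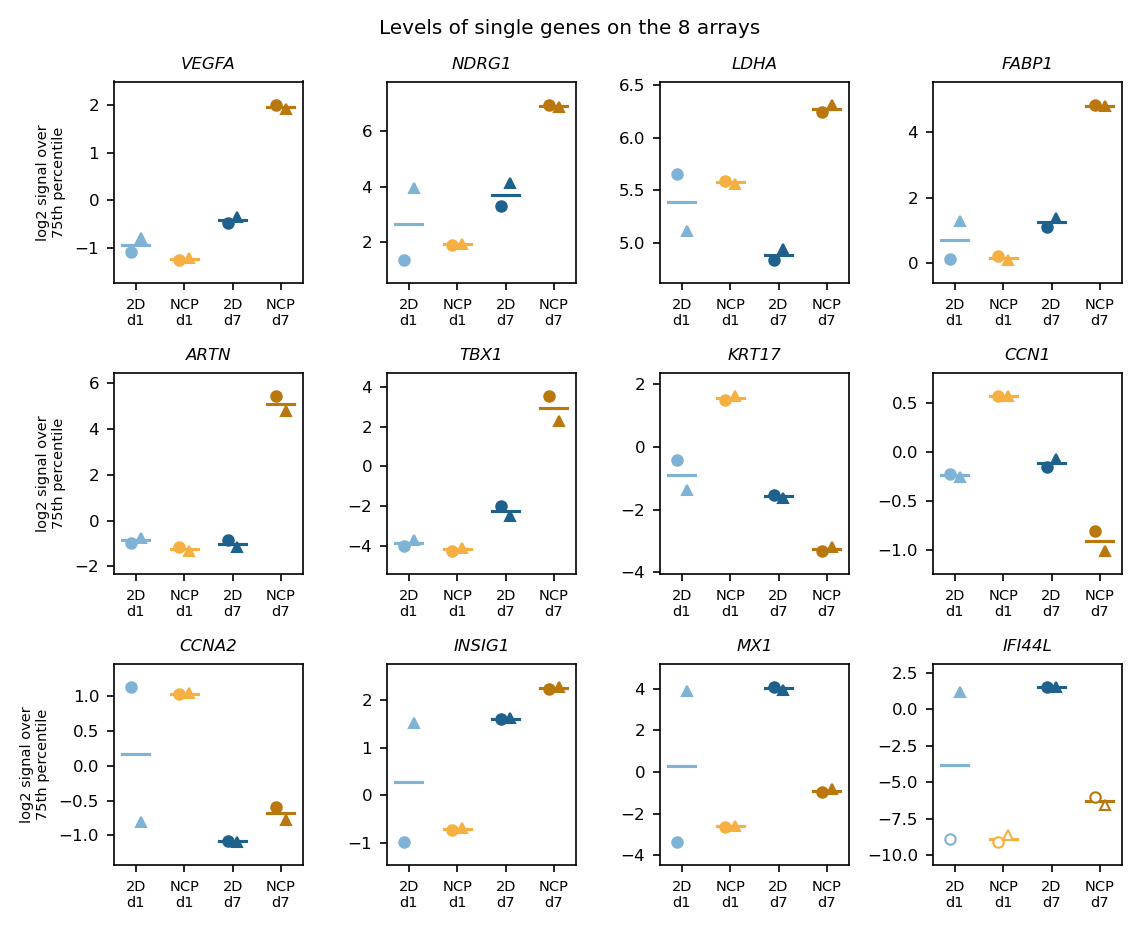
Log2 level relative to the array's 75th percentile for 12 genes in the 4 groups, with a circle for replicate 1, a triangle for replicate 2 and a line at the group mean; open symbols were not well above background. ARTN lies at 5.45 and 4.78 in NCP day 7, and MX1 at -3.35 and 3.90 in 2D day 1.

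The time courses of both plates shared many genes in the 7-array fit. INSIG1 rose and CCNA2 fell in both, and 5623 genes rose in both plates, where 3026 would be shared by chance, while 3590 fell in both, against 1249 by chance. The log2 fold changes over time correlated at 0.659 across genes in that fit, at 0.614 with all 8 arrays and at 0.117 without 2D day 1 replicate 1. Plate effects at day 1 and day 7 correlated across genes at 0.241 with all arrays and at 0.045 in the 7-array fit. Both time courses share no arrays, but genes are not independent replicates. All day 1 arrays lay on slide 1 and all day 7 arrays on other slides, so a slide difference could enter both courses. In the 7-array fit the 2D course also starts from 2D day 1 replicate 1 alone, for which RNA of an NCP day 1 culture stays open. Shared changes therefore cannot be told apart from a shared slide or starting culture.

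The authors' deposited tables gave folds close to the differences of group means computed here from the same arrays. For day 1 the authors' deposited table listed 688 probes, 158 higher and 530 lower in NCP, with KRT16 5.84-fold and KRT17 5.598-fold higher. Of these, 556 stood for a gene here, and 0 were called with all 8 arrays and 110 in the 7-array fit. For day 7 the authors' deposited table listed 508 probes, 317 higher and 191 lower, with IFITM1 92.7-fold lower, ARTN 70.7-fold higher and VEGFA 5.29-fold higher. Of these, 428 stood for a gene here, and 283 were called with all 8 arrays and 427 in the 7-array fit. For NCP over time the authors' deposited table gave 8517 of 41000 probes a corrected p under 0.05, with NDRG1 31.0-fold higher (corrected p 0.0204) and KRT17 28.9-fold lower (corrected p 0.0234). Signs matched those of the group mean differences here, over all probes of a table, for 100%, 100% and 97.8% of probes. The median absolute log2 difference was 0.0376, 0.0229 and 0.0518. The first 2 tables hold only probes at least 2-fold apart on the same arrays, so a match of signs there was bound to be close.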

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

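Chosen only after the result was seen were the 4 tests on the 2D day 1 arrays, the reading of the GC slope within genes for NCP over time, the test of a slide difference behind the GC trend and the test of the culture plate at day 7. The tests of probe GC content within genes at day 7, of the GC trend behind the interferon difference and of lists matched on brightness were chosen before.

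By an interaction term in limma with Benjamini-Hochberg, the difference between NCP and 2D arrays was not the same at day 1 and day 7. At day 7 each plate lay on a slide of its own, so the interaction cannot be told apart from a difference between slides. Between probes of the same gene its slope on GC content was 0.201 per 10 percentage points, against 0.212 across those genes (94.8%). The interaction was called for 1022 genes with all 8 arrays. Fitted values were 6.51 for ARTN, 6.49 for GNG8, 6.24 for FRRS1L and 5.999 for DNAH17. They were -4.44 for KRT17P3, -4.12 for KRT17, -4.004 for KRT16 and -3.83 for KRT83. The sizes for FRRS1L, DNAH17 and KRT83 rest on groups not well above background, and with these at their floor FRRS1L was at least 5.84 and KRT83 -2.06 or lower, while DNAH17 has no bound. Each of these 8 kept its sign on leaving out either 2D day 1 array. With the GC trend removed 494 genes were called, and leaving out any single NCP day 1 or 2D day 7 array left 1 to 4.

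A first pattern was the distance between the arrays labelled 2D day 1. The tables argued against a failed hybridization of the array labelled replicate 2, since its spike-in median coefficient of variation of 3.598% lay within the 3.24% to 10.2% of the other arrays. On the axis from replicate 1 at 0 to 2D day 7 at 1, replicate 2 lay at 0.917. The NCP day 7 arrays lay at 0.793 and 0.828, so a high position is not particular to 2D day 7. The standard deviation of its log2 differences was 0.267 and 0.285 from the 2D day 7 arrays, against 0.771 and 0.656 from NCP day 7. RNA of a 2D day 7 culture under a day 1 label could give these values, although the array was on the slide of the day 1 arrays. That the array labelled replicate 1 holds RNA of an NCP day 1 culture stays open too, since its distance of 0.396 from the nearest NCP day 1 array was above the 0.267 within NCP day 1 and close to the 0.393 within NCP day 7. The gene DZIP1 goes against both label errors. It lay at -3.93 and -3.92 on the arrays labelled 2D day 1 and was not well above background on any other array. As 1 gene picked from many, it settles neither. Cultures that differed between wells may also give a distance of 0.890. As no array was repeated, these explanations cannot be told apart, and a biological difference between wells was not tested.

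A second pattern was the higher level of genes with GC-rich probes on the NCP day 7 arrays. Between probes of the same gene the slope at day 7 was 92.1% of that across genes (95% interval 84.8% to 99.4%). This goes with an effect of the probe in labelling or hybridization in the comparison with 2D day 7. Such an effect would not be particular to the NCP day 7 arrays. Over time the slope between probes of a gene was 0.068 in NCP and -0.132 in 2D. Relative to the mean over all arrays, it was 0.113 and 0.077 on the NCP day 7 arrays. On the 2D day 7 arrays it was -0.092 and -0.101. Within slide 1 it was -0.087 on the array labelled 2D day 1 replicate 2 and 0.024 to 0.036 on the others. In the comparison with NCP day 1 the slope between probes was 23.4% of that across genes (upper end of the 95% interval 29.7%). This argues against such an effect as the main source there, so that changes in the genes themselves remain open. A difference between slides could give the slope of 0.190 per 10 percentage points and cannot be told apart from the plate, since slide 3 held NCP day 7 alone. Position of the probe along the transcript was not separated from GC content.

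A further pattern was the lower interferon response in NCP than in 2D at day 7. The GC trend was argued against as its source, since 97.8% of the list's median was left after its removal in the fit without the array labelled 2D day 1 replicate 2. A shift of all probes of like brightness was argued against too, since the lowest median among 10000 random lists matched on mean signal was -0.42, against -2.74 for the list. The culture plate at day 7 may account for the median of -2.74, but plate, slide and anything else that set these cultures apart cannot be told apart here. Effects of the plate on interferon signalling remain open and untested.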

How the results depend on the processing

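Chosen after seeing the data were removal of the GC trend, that removal without the array labelled 2D day 1 replicate 2, and the crossed block. Where a value below moved or reversed, the cause was not tested, except that fewer arrays or a fold limit set their own counts. A slide block could not be fitted and was not run.

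With all 8 arrays the plate comparison at day 1 had 3 genes. It had 0 in limma under normexp, quantile normalization, median scaling, no filter, the filter on all 8 arrays, trend with robust fitting, the compared groups alone (881 at an unadjusted p under 0.05), the replicate block, GC removal and the crossed block. It had 826 with GC removal without the array, and 0 to 11651 on leaving out each array. At day 7 the 2578 genes became 4897 under normexp, 7089 without a filter, 8947 in the compared groups alone, 1599 with the replicate block, 1617 with the crossed block, 10033 with GC removal without the array and 1300 at a fold of at least 2, and 170 to 10575 on leaving out each array. In NCP over time the 5484 genes became 10772 under normexp, 10028 without a filter, 12711 in the compared groups alone, 13844 with GC removal without the array and 2856 at a fold of at least 2, and 519 to 14238 on leaving out each array. In 2D over time the count was 0 in limma (1712 at an unadjusted p under 0.05), 12014 with GC removal without the array, and 0 to 12069 on leaving out each array. The interaction's 1022 genes became 4399 under normexp, 5004 without a filter, 327 with the replicate block, 336 with the crossed block, 494 with GC removal and 5111 with GC removal without the array, and 1 to 10245 on leaving out each array. The highest counts came from leaving out a 2D day 1 array, with 942 and 11651 at day 1, 12069 and 0 in 2D over time, and 5882 and 10245 for the interaction. Of the calls in NCP over time, 3731 of 5484 were higher at day 7, and this share was 52.8% under median scaling, 53.3% with GC removal and 79.5% under normexp.

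Of 1516 list values 21 reversed. At day 1 on leaving out each array, the medians ran from -0.18 to 1.23 for DNA replication, -0.12 to 1.01 for mitosis, -1.02 to 0.018 for cholesterol synthesis, -3.37 to 0.18 for interferon response, -1.42 to -0.00011 for antigen presentation, -0.27 to 0.31 for immediate early genes, -0.026 to 0.44 for heat shock, -0.11 to 0.45 for NRF2 targets and -0.20 to 0.46 for ribosome biogenesis. With GC removal without the array they were -0.16, -0.11, 0.043, 0.20 and 0.014 for the first 5, -0.014 for heat shock, -0.096 for NRF2 targets and -0.19 for ribosome biogenesis. For the interaction they ran from -0.92 to 0.27 for mitosis (0.27 with GC removal without the array), -2.83 to 0.70 for interferon response and -0.54 to 0.031 for NRF2 targets (0.039). Of 11 list calls at day 7, 7 were kept under normexp and without a filter, 9 under median scaling, 10 with GC removal, and 7 and 8 without an NCP day 7 array. With an estimated correlation 0 lists were called in any comparison, at a lowest adjusted p of 0.126 in camera.

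Of 3588 values of named genes 8 reversed. Under normexp CALD1 was 0.040 at day 7, 0.21 in NCP over time and 0.25 for the interaction, and VIM was 0.17 in NCP over time. KRT14 was -3.26 in NCP over time and -2.65 for the interaction under normexp, against -1.72 and -1.21 with the mean of a gene's probes. The probes of KRT14 thus disagreed in direction, and the brightest probe was chosen anew under normexp. Of 64 named calls at day 7, 56 were kept under normexp, 62 under quantile normalization, 58 with GC removal, 47 with the replicate block, 64 without either 2D day 1 array, 38 without either NCP day 1 array, 12 and 11 without a 2D day 7 array, and 27 and 34 without an NCP day 7 array. For the day 7 comparison, the fits without 1 or the other array of a day 1 group are the same by construction. Signal over background limits genes near the floor, and 65.6% to 71.0% of spots per array were well above it.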
